A study of Rattus norvegicus with 10 samples.

How the data were processed

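Total RNA of cultured Sertoli cells from 20-day-old rats was measured on 10 Affymetrix rat arrays, each reporting 8799 probe sets. Follicle-stimulating hormone (FSH) had been given for 2, 4, 8 or 24 h, and untreated cultures at time 0 were the control. Each of the 5 groups had 2 arrays, labelled replicate 1 and replicate 2. The 2 h array without a number in its label was taken as replicate 1, because its partner is labelled replicate 2. The title of control replicate 1 names no time. It was taken as a 0 h culture because its partner is labelled time 0. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

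The deposited values were linear intensities, 1 per probe set and array, and the labels state no processing. The mean of each array without its lowest and highest 2% lay between 125.2 and 125.27, as scaling of every array to 1 target would leave it. Array medians ran from 26.7 to 44.5 and 75th percentiles from 97.9 to 121. No array shared its values with another. The precision of every comparison is limited by the number of arrays.

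Each array was divided by 0.911 to 1.13 so that all shared a 75th percentile of 107. Values under a floor of 13.4, which is that percentile divided by 8, were set to the floor, and log2 was taken. The 59 control probe sets were left out, and the remaining 8740 were kept where their mean over all 10 arrays reached the pooled median of 31.9. This left 4439 probe sets, of which 3713 carried exactly 1 gene symbol (2733 genes) and 726 did not. Means and SDs in intensity are of the scaled values without the floor. A fold against a group with both arrays at the floor was computed from the floor and is given as a lower bound.

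Gene symbols came from the platform's probe table. It gave 1 symbol for 7006 probe sets, several for 308 and none for 1426. Of the first, 6985 matched a gene of the rat RefSeq table (assembly GRCr8) by gene identifier and 21 did not, and no symbol changed. The array files name no genome build, so no coordinates are given.

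Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on a model with 1 mean per group, which left 5 residual degrees of freedom. Each later time was compared with 0 h, successive times with each other, and 24 h with 2 h. Benjamini-Hochberg adjustment was made within each comparison over all 4439 probe sets, and an adjusted p under 0.05 was called. Errors of log2 changes are limma standard errors (SE), with n = 2 arrays per group. A change at any time was tested with limma's F test over the 4 comparisons with 0 h.

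Gene groups were tested with limma's camera at a preset correlation of 0.01, on the brightest probe set of each gene, for lists with at least 5 tested genes. The 22 lists and 4 times made 88 tests, adjusted together. Camera with an estimated correlation and fry were run beside it. The lists covered immediate early and CREB-target genes, the cAMP pathway, Sertoli secreted and marker genes, steroidogenesis, cholesterol synthesis, glycolysis and lactate, the actin cytoskeleton, cell junctions, proteases and their inhibitors, extracellular matrix, the cell cycle, Id and TGF-beta signalling, antioxidant genes, the circadian clock, retinoid handling, endoplasmic reticulum chaperones, heat shock, inflammatory and NF-kB genes, and ribosomal proteins. Markers of germ, peritubular myoid, Leydig, endothelial and macrophage cells formed further lists. The Leydig and macrophage lists had 4 tested genes each and were counted but not tested.

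Genes were named by a fixed rule. For each time against 0 h it took the 10 largest rises and 10 largest falls among called probe sets with 1 symbol whose treated arrays both lay beyond both controls. For successive times it took the 3 largest of each. Where none was called at a time, the 5 largest changes in each direction among the 50 smallest p-values are given as values. Called members of the lists, and a fixed set of genes linked to FSH action, were added. Tf, Ldha and Per1 have no probe set with a single symbol, and Inhbb, Cyp19a1 and Kitlg lay under the intensity filter, so these were not analysed here. A further gene of that set is not reported here. Samples, comparisons, tests, lists and this rule were all set before the data were examined.

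Replicate numbers were checked for pairing. Deviations from the group means correlated between same-numbered arrays in all 10 pairs of times (r from 0.11 to 0.698). Without the 2 h arrays, one of whose numbers was inferred, the 6 remaining pairs gave 0.205 to 0.608. All 10 arrays lay closest to an array of their own number. The numbers therefore pair the samples, and values from a second fit with the replicate number as a block (4 residual degrees of freedom) stand beside results that it changes. The naming rule was also applied to that fit.

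Changes at different times share the control arrays. Unchanged groups were simulated 100 times against the same controls, with the spread of each group, to give the correlation and overlap without any effect. Both fits were tested on simulated data in 5 draws of 4439 probe sets.

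Alternatives were other scalings (none, median, quantile), other floors or a pseudocount, other intensity filters, other eBayes settings, array weights, only the 4 arrays compared, no 24 h arrays, the replicate block, 1 probe set per gene, stricter thresholds and leaving out each array in turn. Leaving out an array leaves a group of 1, which is assumed to vary like the other groups. These fits had no replicate block, so the difference between numbers enters a comparison with that group. Its error is also wider, so some loss of calls is built into these fits. With 2 arrays per group no regrouping of samples was tested. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, and the genes in them were picked after their values were seen.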

Results

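Cultured Sertoli cells, the somatic cells that nurse germ cells in the seminiferous tubule, were taken from 20-day-old rats and treated with FSH, the pituitary hormone that acts on them through the receptor Fshr and cAMP. Transcript levels were measured on 10 arrays in untreated cultures at 0 h and after 2, 4, 8 and 24 h of FSH, with 2 arrays (n = 2) at each time. No untreated culture was labelled as later than 0 h, so time in culture is not separated from FSH in any change below. Of 8740 probe sets, 4439 were bright enough to test. Replicates of a group correlated across these probe sets at r = 0.867 to 0.905, and the SD of the log2 difference within a pair was 0.978 at 0 h and 0.807 to 0.862 at the later times.

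Arrays also differed by replicate number at every time. Ldhc, the lactate dehydrogenase of spermatogenic cells, had an intensity of 58.5 to 570 on the replicate 1 arrays and 1007 to 1649 on the replicate 2 arrays. Hspa2, a chaperone of meiotic germ cells, had 48.5 to 162 against 448 to 578. Of the 12 germ cell markers tested, 8 were higher in replicate 2, with a median log2 difference of 1.55 over the list. The control ratios of RNA quality moved with the number too: the 3'/5' ratio of beta-actin was 0.928 to 1.17 in replicate 1 and 1.48 to 1.76 in replicate 2. Between the numbers, 674 probe sets differed, 290 higher and 384 lower in replicate 2 by limma. Each time had 1 array of either number, but control replicate 1 stood apart from the other replicate 1 arrays. Its spiked bacterial control CreX had a deposited value of 16221, against 6677 to 8260 on those. Its Ldhc intensity was 570 against 58.5 to 138, though Sycp3, another germ cell marker, had 22.9 against 21.8 to 192. This array enters every comparison with 0 h.

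**Figure D1:**
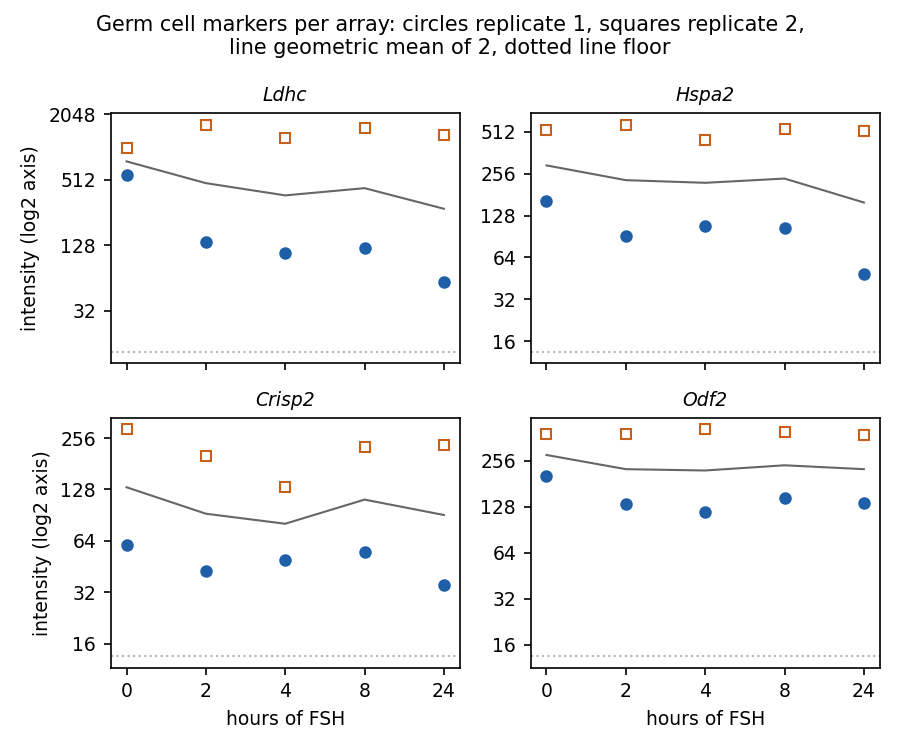
Scaled intensity (log2 axis) of 4 germ cell markers against hours of FSH, with circles for replicate 1, squares for replicate 2, a line for the geometric mean of both and a dotted line for the floor. For Ldhc and Hspa2 every replicate 2 array lies above every replicate 1 array.

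The comparison of 2 h with 0 h asked which transcripts respond first to FSH. The orphan nuclear receptor genes of the Nr4a family rose together. Nr4a1 went from 85.5 ± 21.7 to 1534 ± 513 (mean ± SD intensity, n = 2), 17.7-fold, a log2 change of 4.15 ± 0.60 (SE). Nr4a3 and Nr4a2, both at the floor in the control arrays, rose at least 23.6-fold and at least 16.7-fold. Among other transcription factors, those called and named here rose: Klf4 by 4.58 ± 0.66 log2 units (adjusted p = 0.0151), Cebpb by 3.26, Junb by 2.95, Bmyc by 2.91 (with 1 control array at the floor), Crem by 2.61 and Id3 by 2.41. Another Klf4 probe set had 3.50, which missed the threshold (adjusted p = 0.220) and passed it with the replicate block (adjusted p = 0.00327). Fos rose 5.91-fold on 1 probe set, while another gave a log2 change of 1.70 that missed the threshold (adjusted p = 0.256) and passed it with the replicate block (adjusted p = 0.0101). Some of the called genes limit signalling, namely Dusp1, which dephosphorylates MAP kinases (3.66 log2 units), Errfi1, an inhibitor of the EGF receptor (3.66, with 1 control array at the floor), and Pde4b, a cAMP phosphodiesterase (4.27-fold). The list of the cAMP pathway and its feedback did not shift as a group at 2 h (camera, adjusted p = 0.908). Star, which delivers cholesterol to the inner mitochondrial membrane, rose 7.51-fold, and Plat, the tissue-type plasminogen activator, 6.39-fold. Emd, which encodes the nuclear envelope protein emerin, rose at least 11.8-fold. Txnip, which binds thioredoxin and restrains glucose uptake, fell from 395 ± 97.9 to 73.2 ± 0.474, a log2 change of -2.41 ± 0.33 (adjusted p = 0.0132), and was the only named gene that fell. Nr4a3, Nr4a1, Errfi1, Emd, Bmyc and Id3 also had other tested probe sets, none of which was called at 2 h without the replicate block. With the block the other Nr4a1 probe set was called higher too.

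By limma, 28 probe sets were higher and 2 lower at 2 h than at 0 h, covering 20 named genes, and 203 had an unadjusted p under 0.05. With the replicate block 51 were higher and 3 lower, including all 30. The 28 rises had median log2 changes of 3.34 within replicate 1 and 3.15 within replicate 2, values that the choice of called probe sets keeps apart from 0. Most of the 30 calls were lost when a 0 h or 2 h array was left out, although every one of the 30 kept its direction. Such a fit compares a group of 1 without the replicate block, so part of this loss is built in. The Star call was lost in 8 of the 10 fits that left out 1 array and with the values as deposited (adjusted p = 0.0555).

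The comparison of 4 h with 0 h asked which transcripts had changed by then. Plat rose 15.7-fold, from 28.4 ± 2.39 to 451 ± 101 (log2 change 3.97 ± 0.34, adjusted p = 0.000847). Ptp4a1, a protein tyrosine phosphatase, rose 14.8-fold to 3515 ± 975. Star rose 13.6-fold and Fdx1, the electron donor of the mitochondrial steroidogenic enzymes, 9.99-fold from 246 ± 1.18 to 2467 ± 336. Crem, a source of cAMP-inducible repressors of transcription, rose 11.9-fold, Nr4a3 at least 18.1-fold, Nr4a2 at least 10.9-fold and Nr4a1 9.66-fold. Dgcr6 rose 14.7-fold, LOC102547700 by 3.41 log2 units and Bmyc by 3.35. Smaller rises were those of Ezr, the membrane and actin linker ezrin (6.50-fold), Mvk, the mevalonate kinase of cholesterol synthesis (6.39-fold), Lox, the collagen cross-linking lysyl oxidase (2.38 log2 units, with 1 control array at the floor), and Ocln, the tight junction protein occludin (4.09-fold). The receptor tyrosine kinase gene Ephb3 was at least 14.3-fold higher (adjusted p = 0.0498). A further Nr4a3 probe set had a value in the opposite direction and was not called, and further probe sets of Nr4a1, Fdx1, Mvk, Lox and Ocln were not called either.

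By limma, 38 probe sets were higher and 0 lower at 4 h than at 0 h, covering 27 named genes, and 344 had an unadjusted p under 0.05. With the replicate block 117 were higher and 14 lower. The block falls included Dbp and Nr1d1, which are driven by the circadian clock. Dbp was at the floor on both 4 h arrays and at least 8.75-fold lower (adjusted p = 0.0287 with the block), and Nr1d1 had a log2 change of -1.87 (0.0248). The others included Edn1 (-1.95), Fzd1 (-1.88), Zfp36 (-1.72) and Hmox1 (-1.29). The 38 rises had medians of 3.17 within replicate 1 and 2.73 within replicate 2. Plat, Dgcr6, Crem, Bmyc and Fdx1 were called in all 10 fits that left out 1 array, Nr4a1 and Ephb3 in 2 and Ocln in 0. The count fell to 13 without control replicate 1, 20 without control replicate 2, 8 and 11 without 4 h replicates 1 and 2, 16 without either 8 h replicate, and 25 and 24 without 24 h replicates 1 and 2. With a floor at the 75th percentile divided by 4 the calls of Ephb3, Nr4a2 and Lox were lost (adjusted p = 0.108, 0.0510 and 0.153).

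The comparison of 8 h with 0 h looked at the response later on. Ass1, the argininosuccinate synthase that recycles citrulline to arginine, was at the floor in both controls and reached 484 ± 394, at least 29.5-fold (log2 change 4.88 ± 0.66, adjusted p = 0.0102). Acsl1, which activates long-chain fatty acids, rose 17.6-fold, Plat 19.4-fold, Dgcr6 16.5-fold and Cd24, a surface glycoprotein, 20.2-fold. Inha, the inhibin alpha subunit through which Sertoli cells restrain FSH release, rose 10.3-fold from 214 ± 103 to 2196 ± 1051 (adjusted p = 0.0302). Its change at 4 h, 2.77 ± 0.55 log2 units, missed the threshold (adjusted p = 0.0622) and passed it with the block (adjusted p = 0.00048), with the values as deposited (0.0444) and with quantile normalization (0.0387). At 2 h it was 1.34 log2 units, past the threshold with the block alone (adjusted p = 0.0403). Star stayed 3.46 log2 units above control and Fdx1 9.98-fold, while Lox was 3.54 log2 units higher, Emd at least 13.6-fold and Ckb, the brain creatine kinase, 3.38 log2 units with 1 control array at the floor. Crem, Mvk and Ezr remained called at 6.87-fold, 6.78-fold and 5.99-fold. Emd, Ckb, Fdx1, Mvk and Inha each had another tested probe set that was not called at 8 h without the block. With the block the other Inha probe set was called higher too.

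By limma, 33 probe sets were higher and 1 lower at 8 h than at 0 h, covering 26 named genes, and 413 had an unadjusted p under 0.05. The probe set that fell carries no single gene symbol. With the replicate block 102 were higher and 17 lower, the rises including Dgat1, which makes triglycerides (10.1-fold). The falls included Dbp (at the floor at 8 h, at least 8.75-fold lower) and, in log2 units, Irgm2 (-2.45), Schip1 (-2.38), Cdo1 (-1.99) and Nr1d1 (-1.36). This Nr1d1 value is from another probe set than the one given for 4 h, which fell further at 8 h in that fit. Plat, Dgcr6 and Emd were called in all 10 fits that left out 1 array, Inha in 4 and Cd24 in 2. The count fell to 11 without control replicate 1, 22 without 4 h replicate 1, 5 without 8 h replicate 1 and 13 without 8 h replicate 2. With a floor at the 75th percentile divided by 4 the Ckb call was lost (adjusted p = 0.0555).

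**Figure D2:**
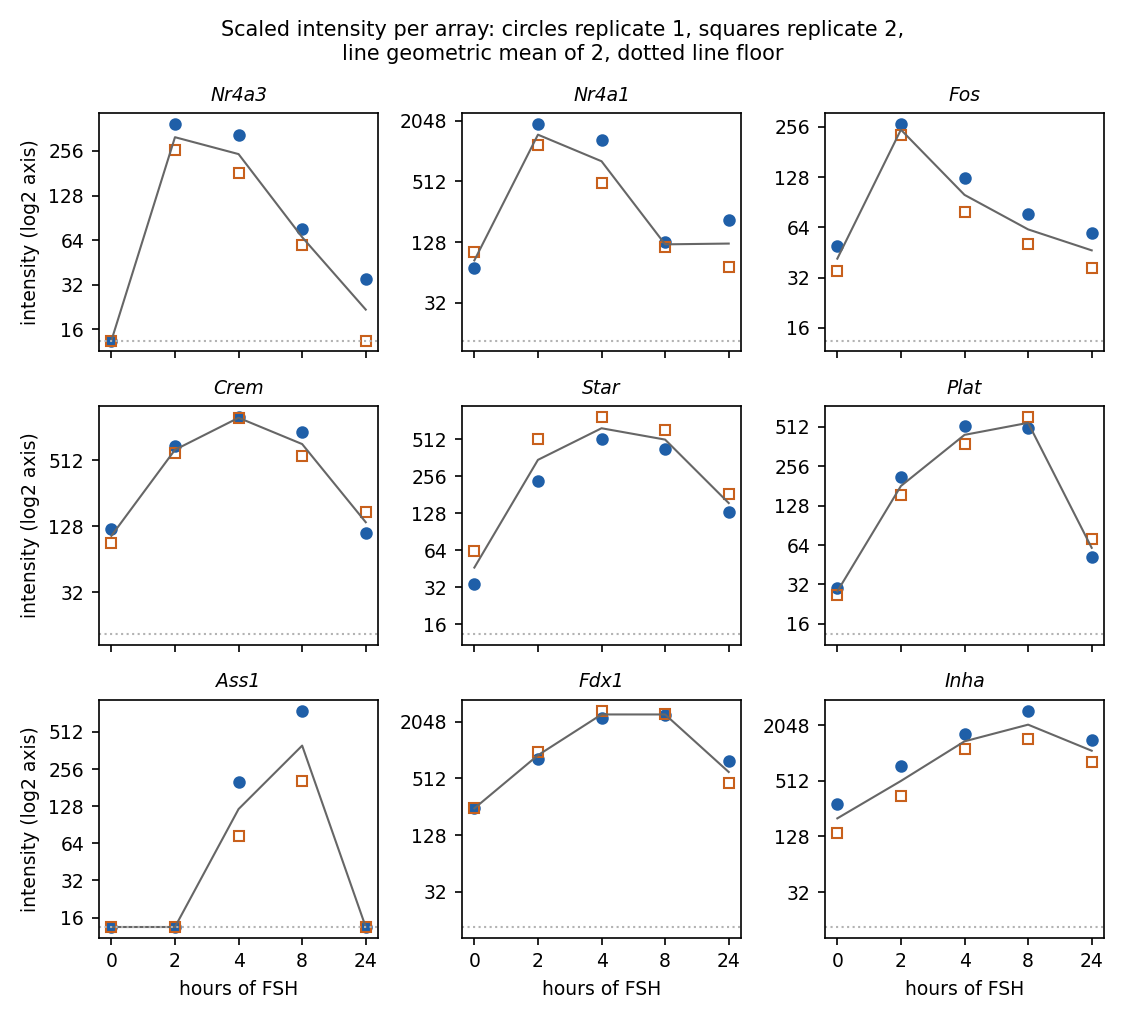
Scaled intensity (log2 axis) of 9 genes against hours of FSH, with circles for replicate 1, squares for replicate 2, a line for the geometric mean of both and a dotted line for the floor. Nr4a3, Nr4a1 and Fos are highest at 2 h, and Ass1 returns to the floor at 24 h.

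After 24 h no probe set was called against 0 h by limma, with 204 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0659. The values of the largest changes were 3.17 ± 0.64 log2 units for Wfdc1, a whey acidic protein family member, 2.81 ± 0.46 for Fam229a, 2.58 ± 0.34 for Bmyc, 2.43 ± 0.55 for Inha and 2.21 ± 0.59 for Calca, and -2.35 for Pla2g5, -2.28 for Adm, -2.13 for Cst8, -2.08 for Krt18 and -1.76 for Zfp36. For Bmyc, Calca, Pla2g5, Adm and Cst8 1 of the 4 arrays was at the floor. With the replicate block 4 probe sets were higher and 0 lower, namely Wfdc1 and Bmyc (adjusted p = 0.0234 each), Inha (0.0140) and a further Star probe set (2.99 log2 units, 0.0140). Bmyc also passed with quantile normalization (adjusted p = 0.0152). The limma F test over all times called 44 probe sets, and 143 with the block. That count fell to 26 without 2 h replicate 1, 23 and 28 without 4 h replicates 1 and 2, and 19 and 20 without 8 h replicates 1 and 2. On simulated data for this comparison, limma recovered 90.3% of rises of 3 log2 units, 49.4% of rises of 2 and 1.18% of rises of 1 among 4439 probe sets, and with the block 100%, 90% and 15.9%. Falls of the same sizes were recovered in 64.2%, 36.4% and 1.21%, and with the block in 78.2%, 80% and 16.4%. The simulated arrays shared 1 spread per probe set, while the residual SD of the 0 h arrays was 1.38 of the mean over all arrays. Many simulated probe sets also changed at every time, which eases the adjusted threshold. Their difference between numbers was the same at every time, as the block fit assumes. These recoveries may therefore be too high for the measured arrays.

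**Figure D3:**
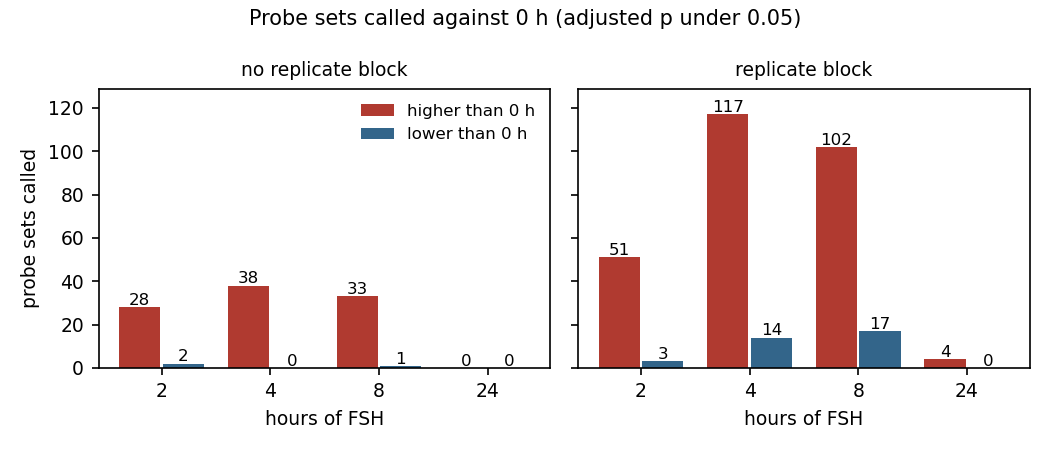
Number of probe sets called higher (red) or lower (blue) than 0 h against hours of FSH, without the replicate block on the left and with it on the right. Without the block 28, 38 and 33 probe sets were higher at 2, 4 and 8 h and 0 at 24 h.

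Successive times were compared directly. Between 8 and 24 h, 10 probe sets fell and 0 rose. Ass1 fell by 4.88 ± 0.66 log2 units, back to the floor and at least 29.5-fold lower (adjusted p = 0.0258), Acsl1 fell by 3.97 ± 0.47 and Crem by 3.69 ± 0.36 (adjusted p = 0.0109 for both). The others were Plat, Mvk, Dgcr6, Dgat1, LOC102547700, Emd and Gchfr, the feedback regulator of GTP cyclohydrolase, named after their values were seen. With the replicate block 41 fell and 10 rose, the rises including Dbp (at least 15.6-fold) and Nr1d1 (4.03-fold). The 10 calls became 5 without either 2 h replicate, 6 without either 4 h replicate, 0 without either 8 h replicate, 2 without 24 h replicate 1 and 0 without 24 h replicate 2. No probe set was called by limma between 2 and 4 h (160 at an unadjusted p under 0.05, 0 with the block) or between 4 and 8 h (152 at an unadjusted p under 0.05). With the block 4 fell between 4 and 8 h, among them Ocln, which fell by 2.64 (adjusted p = 0.0432).

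Whether the early response had returned towards control was asked by comparing 24 h with 2 h. Of the 30 probe sets called at 2 h, 12 were lower and 1 higher at 24 h than at 2 h. Nr4a3 fell by 3.86 log2 units (adjusted p = 0.0153), the lower ones also included Nr4a2, Junb, Id3, Crem, Errfi1 and Emd, and the higher one was Txnip (2.19, adjusted p = 0.0331). With the block 29 of 54 were lower and 1 higher. The 13 became 7 without control replicate 1, 2 without control replicate 2, 0 and 3 without 2 h replicates 1 and 2, and 5 and 0 without 24 h replicates 1 and 2. The rises called at 2 h kept a median of 19.5% of their log2 change at 24 h, and those called at 4 h kept 16.8%. Probe sets chosen for a high value at 2 or 4 h would lie lower later by that choice alone, which limits this comparison.

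Star, Ptp4a1, Plat, Dgcr6, LOC102547700, Crem, Emd and Bmyc were called higher at each of 2, 4 and 8 h. Between 2 and 4 h 17 called rises were shared, where independent lists would share 0.24, and between 4 and 8 h 21, against 0.282. Simulated unchanged groups on the same controls shared 0, but they give hardly any calls, so this count does not measure what the controls add. Across probe sets, which are not independent replicates, the changes at 2 and 4 h had a covariance of 0.287, against 0.156 simulated without any effect, and those at 4 and 8 h had 0.356 against 0.155. Those at 2 and 8 h had 0.241 against 0.156 and those at 8 and 24 h 0.215 against 0.155, while 2 and 24 h had 0.159 against 0.156 and 4 and 24 h 0.168 against 0.155. The correlations lay above the simulated ones for 2 and 4 h (0.726 against 0.680) and for 4 and 8 h (0.744 against 0.718). They lay below them for 2 and 8 h (0.578 against 0.708), 2 and 24 h (0.502 against 0.694), 4 and 24 h (0.463 against 0.704) and 8 and 24 h (0.561 against 0.733), although any separate spread of the changes lowers a correlation and leaves the covariance. With each change taken from 1 array and the control of its own number, no control was shared. The correlation was then -0.0181 for 2 and 4 h and 0.171 for 4 and 8 h, where single arrays add noise. Noise separate for each array does not lower the covariance. That was -0.0133 for 2 and 4 h, -0.00638 for 2 and 8 h and 0.130 for 4 and 8 h. The 2 changes came from opposite replicate numbers, so a difference between numbers shared by treated times but not by 0 h lowers this covariance. Deviations at 2 and 4 h correlated at 0.698, against 0.11 and 0.205 with those at 0 h. Without shared controls an excess was thus seen for 4 and 8 h and not for 2 and 8 h. For 2 and 4 h this check cannot decide, because that shared difference lowers the value. Part of the excess over independent lists may come from the shared controls.

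Several genes linked to FSH action were not called at any time by limma. Clu, the abundant secreted clusterin, had log2 changes of -0.15, 0.03, -0.12 and -0.38 at 2, 4, 8 and 24 h, with a control intensity of 10738 ± 4305. Shbg, which encodes androgen-binding protein, had 0.19, 0.20, 0.21 and -0.26. Fshr itself had -0.32, -0.50, -0.95 and -0.66, Amh -0.36, -0.24, -0.41 and -0.66, Inhba 0.15, 0.64, 0.30 and 0.22, and Id2 1.57, -0.10, 1.10 and -0.48. Scarb1, a receptor for lipoprotein cholesterol, had -0.15, 2.16, 2.86 and 1.18, with the 8 h value past the threshold with the block (adjusted p = 0.0455).

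Immediate early and CREB-target genes, those transcribed at once when cAMP or growth signals arrive, shifted upwards as a group at 2 and 4 h. On the brightest probe set of each gene, 6 of 27 tested members rose at 2 h (Junb, Nr4a3, Crem, Nr4a2, Nr4a1 and Cebpb), and 9 with the replicate block. Klf4, Dusp1 and Fos, also members, were called without the block only on other probe sets. Adjusted over the list alone 11 were higher and 2 lower, and the list had a median log2 change of 0.87 (camera, adjusted p = 3.1e-11). With an estimated correlation the adjusted p was 0.590, and by fry 0.170. At 4 h 4 members rose, or 5 adjusted over the list alone, with a median of 0.46 (camera, adjusted p = 0.000366). With the replicate block 7 rose at 4 h, or 10 higher and 1 lower adjusted over the list alone. With an estimated correlation the adjusted p was 0.769, and by fry 0.213. Without 4 h replicate 1 the adjusted p at 4 h was 0.0656.

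Inflammatory and NF-kB genes shifted downwards as a group at 24 h, with a median log2 change of -0.74 over 14 tested members (camera, adjusted p = 0.00709). With an estimated correlation the adjusted p was 0.769, and by fry 0.436. None of its members was called, nor was any adjusted over the list alone. Socs3, an inhibitor of cytokine signalling, had -2.36, Lcn2, the iron-binding lipocalin, -1.55, the chemokine gene Cxcl10 -1.51 and Stat3 -1.08, while Nos2 had 0.77 and Nfkb1 0.74. The adjusted p was 0.235 without control replicate 1, 0.135 without 24 h replicate 2 and 0.0709 without the intensity filter. Germ cell markers had a median of -0.32 at the same time and the beta-actin 3'/5' ratio was 1.01 and 1.73 on the 24 h arrays.

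Of the 88 tests of gene groups these 3 passed the threshold, 0 with an estimated correlation, 0 by fry and 5 with the replicate block. The number was 7 without control replicate 1, 8 without control replicate 2, 5 without 2 h replicate 2 and 6 without 24 h replicate 2. The block added extracellular matrix genes, higher at 24 h with a median of 0.26 (adjusted p = 0.0241 with the block and 0.113 without), and germ cell markers, lower at 24 h with a median of -0.32 (0.0241 and 0.199). With an estimated correlation both had an adjusted p of 0.759 in the block fit. Col3a1 had 2.15, Col1a2 2.05 and Fn1 1.40 log2 units at 24 h, none of them called. Markers of peritubular myoid cells, which make matrix around the tubule, had a median of 0.79 at 24 h (adjusted p = 0.113), with Acta2 at 1.84 and Tagln at 1.68.

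The remaining groups did not pass, and the smallest adjusted p of each over the 4 times follows. Glycolysis and lactate genes had 0.113 at 2 h (median -0.28), and steroidogenesis genes 0.179 at 4 h, when Star and Fdx1 rose among 12 members. The Sertoli secreted and marker genes had 0.350, the cAMP pathway 0.775, cholesterol synthesis 0.575, the actin cytoskeleton 0.145, cell junctions 0.386 and proteases and their inhibitors 0.145. For the cell cycle it was 0.179, for Id and TGF-beta signalling 0.145, for antioxidant genes 0.575, for the circadian clock 0.145 and for retinoid handling 0.515. Endoplasmic reticulum chaperones had 0.178, heat shock genes 0.515, ribosomal proteins 0.386 and endothelial markers 0.179. Among the 4 Leydig cell markers measured Star alone rose, at 2, 4 and 8 h, and none of the 4 macrophage markers was called at any time.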

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

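The tests of explanations in this part, except that of bright probe sets, were chosen after the result was seen.

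Levels differed between the treated times by direct contrasts, in which time in culture is not separated from FSH. Between 8 and 24 h the change from 0 h differed for 10 probe sets, with Ass1, at the floor at 24 h, at -4.88 or lower, Acsl1 at -3.97 and Crem at -3.69 log2 units, and between 2 and 24 h it differed for 14. Signal outside the tested probe sets was also seen: among those under the intensity filter, 3 were called higher at 2 h than at 0 h, 11 at 4 h and 3 at 8 h, and 8, 10 and 8 lower, with 0 higher and 4 lower at 24 h. Nearly all of those that rose had a control mean under the floor, such as Kazn, which went from 5.71 ± 2.72 to 42.5 ± 0.138 at 4 h, while Ptprh, with a control mean just above it, went from 14.2 ± 8.49 to 86.3 ± 30.3 at 8 h. Setting values to the floor shrinks the spread on which their p-values rest.

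Arrays split by replicate number. A difference in RNA integrity or labelling may be behind it: the lowest beta-actin 3'/5' ratio of the replicate 2 arrays lay 0.308 above the highest of the replicate 1 arrays. A larger share of germ cells in the replicate 2 cultures may be behind it as well, since germ cell markers stood apart from other genes between the numbers with a camera p of 0.0104 at an estimated correlation, although the adjusted p over all lists was 0.228. Ldhc had 1007 to 1649 against 58.5 to 570, and none of the 12 tested markers is on another list. Both concern how the samples were prepared. Neither excludes the other, and no further explanation was tested because the labels give no source for the numbers.

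Called rises outnumbered falls at 2, 4 and 8 h among the tested probe sets. Without the intensity filter the split was 14 to 9, 31 to 11 and 25 to 9, with most falls among probe sets under the filter. A floor that hides falls of dim probe sets predicts at least as many falls as rises among bright ones, yet among 2222 probe sets with a control mean at or above the 75th percentile 13 rose and 3 fell (two-sided exact binomial p = 0.0213), or 67 and 29 with the replicate block (p = 0.000132). These p-values treat probe sets as independent, which they are not. On simulated data limma recovered 64.2% of falls of 3 log2 units at 24 h against 90.3% of rises, so the floor is argued against as the whole of the excess and not as a part of it. A shift by the choice of scaling was argued against: called falls would reach called rises only if all changes were lowered by at least 0.68 log2 units, while the median change differed by at most 0.179 between 4 scalings. Under each of these scalings 93.3% to 100% of the calls at 2, 4 and 8 h were rises. A common change of most transcripts, which every scaling removes, was not tested and stays open.

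Few probe sets were called at 24 h. Noise of the 24 h arrays was argued against, as their residual SD was 0.853 of the mean over all arrays in the fit with the replicate block. Fading of the early response may account for part of it: 84.2% of the probe sets called higher at 4 h lay lower at 24 h than at 8 h, 7 of 38 by the test. The control arrays, which had the widest spread (1.38 of the mean), enter every comparison with 0 h but not that of 24 h with 8 h.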

How the results depend on the processing

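All alternatives in this part were planned before the data were examined.

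With each result counted against its alternatives other than leaving out an array, 112 counts, correlations and list totals stayed within the limits and 54 moved. Leaving out 1 array left a further 61 within them and moved 39. The direction of the calls did not enter the limits for counts. Scalings and eBayes settings left the counts at 2, 4 and 8 h within 1.5 times, array weights excepted. Median scaling moved the median of all probe sets to 0.105 at 8 h and 0.185 at 24 h, against -0.025 and 0.018. Signal over background limits what can be seen: a fall of a probe set near the floor cannot be measured. Values follow for 2, 4, 8 and 24 h against 0 h, the intervals, any time, the probe sets called at 2 h that differ at 24 h, and gene lists; the cause was not tested unless stated.

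With the replicate block counts were 54, 131, 119 and 4, then 4 between 4 and 8 h and 51 between 8 and 24 h, 143 at any time, 30 and 5 lists; without the 2 h arrays the block gave 114, 103 and 5 at 4, 8 and 24 h, then 4 and 46. It ended no call of a probe set. Testing 1 probe set per gene gave 15, 21 and 20 at 2, 4 and 8 h, 27 at any time and 4. The main fit called 20, 27 and 26 named genes at 2, 4 and 8 h, so genes were lost too. Some, such as Klf4, Dusp1 and Fos at 2 h, had been called only on a probe set other than the brightest. An adjusted p under 0.01 gave 7, 15 and 11, then 0 between 8 and 24 h, 16 at any time and 1, by construction. Only the 4 arrays compared gave 9, 23 and 18, then 0 between 8 and 24 h and 0, with 2 residual degrees of freedom. Without the 24 h arrays 25 were called at 4 h. Array weights gave 16 at 4 h, 22 at 8 h and 26 between 8 and 24 h. At 24 h median scaling gave 2 and quantile normalization 2, and the latter gave 16 between 8 and 24 h. A floor at the 75th percentile divided by 4 gave 17 there. No intensity filter gave 4 at 24 h, all lower, where median scaling, quantile normalization and the block gave rises alone, 14 between 2 and 4 h, 13 between 4 and 8 h, 2 between 8 and 24 h, 5 and 6 lists. A filter at the 75th percentile gave 1 at 24 h and 29 at any time. Camera with an estimated correlation and fry gave 0 lists each. With each control array serving 1 comparison, and each change taken from 1 array and the control of its own number, which adds noise, the correlations were -0.0181 (2 and 4 h), -0.00884 (2 and 8 h), -0.088 (2 and 24 h), 0.171 (4 and 8 h), -0.0526 (4 and 24 h) and 0.0471 (8 and 24 h).

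Leaving out 1 array gave 0 to 31 at 2 h, 8 to 28 at 4 h, 5 to 26 at 8 h, 0 to 0 at 24 h, between 2 and 4 h and between 4 and 8 h, 0 to 15 between 8 and 24 h, 19 to 37 at any time, 0 to 12 of those called at 2 h, and 2 to 8 lists. Among named genes, 831 of these values kept their side of the threshold and 169 lost it. All the lost ones lay among the 510 values called in either fit, as the rest had no call to lose. Of these 510, 0 turned direction, which the choice of called changes favours, and of those called in neither 25 did. No value could be had for the F test with 4 arrays, for 24 h without the 24 h arrays, or for 2 h in the block without the 2 h arrays.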

Other observations

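The test reported in this part beyond the fixed comparisons, the naming of genes in the fit with the replicate block, was chosen after the counts were seen.

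Of the 6 tested genes of the circadian clock none was called at 8 h without the replicate block, and the list did not pass, with a median of -0.80 (camera, adjusted p = 0.145, and 0.769 with an estimated correlation). Adjusted over the list alone 1 was higher and 3 lower. Bmal1, the activator of the clock, had a log2 change of 2.18 ± 0.62, while Dbp and Nr1d1, which it activates, fell in the fit with the replicate block, Dbp to the floor and at least 8.75-fold (adjusted p = 0.0319) and Nr1d1 by 2.28 log2 units (0.00885). A second probe set of Dbp had -1.76 and was not called, and a second of Nr1d1 fell by 1.36 in that fit (0.0298). The clock output factor Tef had -1.09. From 8 to 24 h the first probe sets of Dbp and Nr1d1 rose in that fit by at least 3.96 and by 2.01 log2 units, and the second ones were not called. The labels give no hour of collection and no untreated culture later than 0 h, so time in culture and FSH were not separated.

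Other genes, named after their values were seen, passed the threshold in the fit with the replicate block alone. Pde4d, a cAMP phosphodiesterase like Pde4b, had log2 changes of 2.80, 2.72 and 2.44 at 2, 4 and 8 h (adjusted p = 0.00298, 0.00366 and 0.00658 with the block). Asns, the asparagine synthetase, had 2.22 at 4 h and 3.20 at 8 h (0.0014 and 0.000148), the NF-kB subunit Nfkb1 2.78 and 2.24 (0.00126 and 0.00427), and the tropomyosin Tpm4 1.56 and 2.05 (0.0305 and 0.00817). Rdh10, which oxidizes retinol, had 1.98 at 8 h (0.0209), and Pfkfb4, a regulator of glycolysis, 1.26 at 4 h (0.0424). On simulated data the block fit called 28 to 38 of 21195 unchanged probe sets per time over 5 draws, against 0 to 2 without it. The simulation gave each probe set 1 difference between numbers, the same at every time, as the block fit assumes. In the measured arrays deviations at 0 h correlated with those at 2 and 4 h at only 0.11 and 0.205. The block fit may therefore do worse on the measured arrays than in this simulation. At 2 h its 28 stood beside 150 called rises of 2 log2 units and 165 of 3. Without the block 86 and 147 of these rises were called.

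Acsl1 and Dgat1, both steps towards stored triglyceride, were 17.6-fold and 10.1-fold above control at 8 h and fell between 8 and 24 h, Dgat1 from 2382 ± 322 to 255 ± 12.0. Hagh, a glyoxalase, fell by 2.63 and the intermediate filament gene Nefh by 2.90 in the fit with the block over the same interval. Tyro3, a receptor of phagocytosis in Sertoli cells, rose by 2.05 in that fit, while its other probe set had a value in the opposite direction and was not called. Igf2r rose by 1.77 in that fit.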
